A study of Mus musculus with 6 samples.

How the data were processed

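RNA was measured in 6 libraries of CD4+ T cells isolated with a kit from mouse spleen, 3 labelled allogeneic and 3 labelled syngeneic haematopoietic stem cell transplantation. Per the labels' protocols, ribosomal RNA was removed from total RNA before library construction. The group of each library was taken from the characteristics labels, which name C57BL/6 donors and BALB/c hosts for the allogeneic group and BALB/c donors and hosts for the syngeneic group. The sample titles carry the letter S for the libraries labelled allogeneic and A for those labelled syngeneic, and the groups follow the characteristics throughout. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

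The deposited table gives 1 value per gene and library, which the values show to be FPKM (or RPKM, since nothing says whether reads or fragments were counted). A gene's value times its merged exon length in GENCODE M21 (genome build GRCm38) was a whole multiple of 1 step per library, within a tolerance of 0.05 reads, for 14580 of the 15686 genes (92.9%) in all 6 libraries. The column totals differed between libraries, so the values were not TPM. The lowest maximum of any gene over the libraries was 0.517 FPKM. The aligner, counter, genome build and annotation of the authors are not given in the sources used here, and the submitters' processing notes name limma. Coordinates are from GENCODE M21 and build GRCm38, the reference used here, in which 15672 of the 15686 gene identifiers were found.

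The step gave an implied depth of 16.3, 16.2 and 15.7 M reads in the libraries labelled allogeneic and 16.96, 16.87 and 14.8 M in those labelled syngeneic. Replicate libraries of a group differed by more than sampling noise, with a median chi-square per gene between 2.40 and 3.60 times that of counting error, so each library was counted separately. This comparison, the simulation and the added voom test treat reads as independent counts, although amplification copies were not marked.

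Genes with at least 1 FPKM in at least 3 libraries (13235) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, libraries labelled allogeneic minus libraries labelled syngeneic, and understate the change of low genes. Fixed gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 51 lists covering 798 genes (T cell programmes, cell cycle, metabolism, stress, other cell types, quality and strain checks), 44 with at least 5 measured genes were tested, and the adjustment ran over those 44. The share of superantigen-sensitive T cell receptor beta segments was compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3.

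The lists, tests and the rule for naming genes were chosen before the data were examined. Among genes past the test with a log2 fold change of at least 1 in size and groups that did not overlap, the rule took the 10 largest rises and 10 largest falls in the upper 25% by mean level, leaving out receptor and immunoglobulin segments, pseudogenes and unnamed loci. It added the 5 higher and 5 lower genes with the smallest adjusted p, up to 4 examples per list (the largest changes, at most 2 per direction where both occurred, or all members of a list of at most 6) and all genes of the strain check. The 4 CD3 chain genes, ribosomal protein genes and pseudogenes named outside this rule were chosen after their values were seen. Some genes that the rule takes are not reported here.

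The limma step was tested on simulated reads drawn for the real genes from the libraries' means and depths. With no change it called 0 of 12294 genes. With 200 changed genes among 12304 it recovered 86% of those changed 1.5-fold and 98% of those changed 2-fold, and 7.54% of the 199 called genes were unchanged. The simulation drew genes independently with a fixed dispersion of 0.002 and few changed genes, whereas 67.4% of tested genes were called in the data. It therefore does not give the error rate or power in these data.

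Alternatives were quantile normalization, equal upper quartiles, no filter and a stricter filter on low values, pseudocounts of 0.1 and 5, limma without the trend, a fold threshold, the replicate number as a block, leaving out each replicate in turn, and rescaling without cell type and immunoglobulin genes. Added after the data were seen were voom in limma on the recovered reads, scaling of FPKM to the geometric mean of the 4 CD3 chains of each library, and subtraction of the median fold change. Pseudogenes were matched to parent genes with BLAST+ 2.17.0 at 85% identity or more. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, the alpha globin pair, Aldoa (2 entries), Gapdh and the H2-Q, Gbp, Oas and Bcl2a1 families, are uncertain, because the way the authors divided shared reads is not given in the sources used here.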

Results

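The data were FPKM values of 15686 genes in spleen CD4+ T cells from mice after haematopoietic stem cell transplantation, a setting in which donor T cells that differ from the host can cause graft-versus-host disease. In allogeneic transplantation donor and host differ genetically, and in syngeneic transplantation they are alike. There were 3 libraries labelled allogeneic (C57BL/6 donor, BALB/c host) and 3 labelled syngeneic (BALB/c donor and host), with an implied depth of 14.8 to 16.96 M reads each. The design asks which genes and pathways differ between allogeneic and syngeneic CD4+ T cells. Pearson correlation of log2 values across genes was 0.987 to 0.989 within groups and 0.881 to 0.886 between them, where genes are not independent replicates, and the first principal component held 87.3% of the variance.

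Genes that differ between the 2 donor strains were read first, as a check of the labels, and 8 of the 9 measured went against them. Trbv26 is a T cell receptor beta segment whose bearers are deleted in BALB/c mice by endogenous viral superantigens. It was at 0.402 ± 0.438 FPKM (SD, n = 3) in the libraries labelled allogeneic, where C57BL/6 was named as the donor strain. In those labelled syngeneic it was at 56.5 ± 3.25. Trbv15 (1.57 against 39.9 FPKM), Trbv16 (3.33 against 52.9), Trbv12-1 (1.40 against 8.31) and Trbv12-2 (9.28 against 17.01), other segments of this kind, were also lower in the libraries labelled allogeneic. Hosts in both groups were named as BALB/c. Among the other segments Trbv23 (−2.80), Trbv3 (−2.75) and Trbv14 (−1.90) fell on the log2 scale as well, against −1.98 for Trbv12-1 and −0.79 for Trbv12-2. Scaled to the CD3 chains, Trbv12-2 was at a log2 difference of 0.21 and no longer past the test. Together the 5 segments made up 4.91% ± 0.416 of Trbv FPKM in the libraries labelled allogeneic and 26.5% ± 1.46 in those labelled syngeneic (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest this design allows). Reads of Trbv26 numbered 0, 2 and 5 in the 3 libraries labelled allogeneic against 340, 338 and 328. Ighg2c, the IgG heavy chain gene carried by C57BL/6 in place of the BALB/c allotype (chromosome 12, 113285325 to 113288932), stood at 16.3 ± 0.247 against 9605 ± 270 FPKM. IgG genes that were not chosen as strain markers fell with it, Ighg1 by 7.15, Ighg2b by 6.56 and Ighg3 by 2.82 on the log2 scale. Without Ighg2c 7 of 8 strain genes went against the labels, and without the Trbv segments as well 2 of 3. Ly6a, a surface antigen known to be higher on C57BL/6 T cells (chromosome 15, 74994877 to 74998031), stood at 32.9 ± 1.66 against 329 ± 33.9 FPKM. H2-Ea-ps, whose transcription C57BL/6 mice lack, was at 133 ± 3.02 FPKM in the libraries labelled allogeneic and 21.1 ± 2.73 in those labelled syngeneic. Gbp2b, known to be higher in BALB/c, went with the labels at 18.5 ± 0.613 against 31.3 ± 1.07 FPKM, and its direction turned to 0.32 on the log2 scale after scaling to the CD3 chains. The class I genes H2-K1 (−1.66), H2-Q7 (−1.85), H2-Q6 (−1.28), H2-Q4 (−0.81) and H2-D1 (−0.70) all fell in the libraries labelled allogeneic on the log2 scale, and scaling to the CD3 chains turned H2-D1 to 0.39 and H2-Q4 to 0.27. All directions below are between libraries as labelled, and this disagreement stands beside each of them. Xist, read as a check of sex, was at 95.9 ± 2.36 against 74.2 ± 1.60 FPKM.

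**Figure D1:**
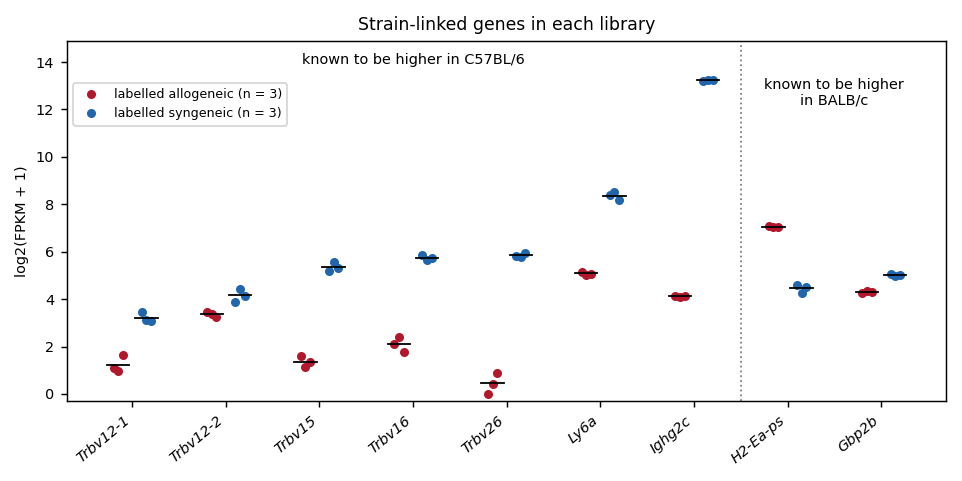
Expression of 9 strain-linked genes as log2(FPKM + 1) in each of the 6 libraries, with 3 points per group (red, labelled allogeneic; blue, labelled syngeneic) and black bars for group means. Trbv26 lay at 0.402 against 56.5 FPKM and Ighg2c at 16.3 against 9605 FPKM, and Gbp2b alone went with the labels for FPKM as deposited, while scaling to the CD3 chains turned Gbp2b and Trbv12-2.

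Between the groups as labelled, 15 of 17 cytotoxic genes and 13 of 15 inhibitory receptor genes were lower in the libraries labelled allogeneic and all 17 red cell genes were higher. The CD8 T cell marker Cd8b1 fell with them, from 11.8 ± 0.970 to 1.37 ± 0.146 FPKM. For these 3 lists camera gave adjusted p = 2.10e-06, 3.36e-06 and 1.08e-07, and adjusted p = 0.0645, 0.0718 and 0.0645 with an estimated correlation. Gzmb, which encodes the cytotoxic protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), fell from 271 ± 9.76 FPKM in the libraries labelled syngeneic to 24.8 ± 0.881 in those labelled allogeneic (log2 fold change −3.40, SE 0.0415, n = 3 each, limma with Benjamini-Hochberg adjusted p = 5.01e-08). Pdcd1, the inhibitory receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), fell from 59.2 ± 0.71 to 6.29 ± 1.02 FPKM (−3.06, SE 0.0936, limma adjusted p = 9.13e-07). Tigit, another inhibitory receptor (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146), fell from 135 ± 4.60 to 18.4 ± 0.991 (−2.81, SE 0.0484, limma adjusted p = 1.65e-07). In the other direction the beta globin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) rose from 1.58 ± 0.637 to 176 ± 3.63 FPKM (6.14, SE 0.169, limma adjusted p = 5.86e-07). Mpo, the myeloperoxidase of granulocyte precursors (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), rose from 42.6 ± 8.08 to 674 ± 24.2 FPKM (3.97, SE 0.128, limma adjusted p = 1.11e-06).

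Other large rises among well expressed genes were those of the globins Hba-a1 (5.44 on the log2 scale) and Hbb-bt (4.77) and of Ly6c1 (3.52), an antigen of monocytes and some T cells. Hmox1, haem oxygenase, rose by 2.82, Csf3r, the receptor of a granulocyte growth factor, by 2.81, and Lmo2, a regulator of blood progenitors, by 2.61. Fcna (2.79) and Cd5l (2.49), both macrophage products, rose too. Among the large falls, Serpinb6b (−3.76) and Serpinb9 (−2.68) encode intracellular protease inhibitors, and Chil3 (−3.37) a secreted myeloid protein. Rpl29 (−5.55), Rps2 (−3.58) and Rpl26 (−2.67), ribosomal protein genes, share sequence with pseudogenes, and their values are uncertain. Ly6a also fell, by 3.28. By smallest adjusted p the list also held Csf1r (2.35) and Slc4a1 (3.65) among genes that rose, and Neb (−3.22), which encodes a muscle filament protein, and Fkbp5 (−1.91), a steroid-induced chaperone partner, among those that fell. In all, limma with Benjamini-Hochberg adjustment called 8914 of 13235 genes (67.4%), 5389 higher and 3525 lower, and groups did not overlap for 72.5% of genes where chance gives 10%. Equal upper quartiles moved the split of calls to 4495 higher and 4416 lower, and median subtraction to 4556 and 4367. Immunoglobulin segments held 9.03 to 9.28% of FPKM in the libraries labelled allogeneic and 24.8 to 26.1% in those labelled syngeneic.

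The receptor machinery of T cells was lower as a group for FPKM as deposited, and its list median turned positive after scaling to the CD3 chains. Of 20 measured T cell receptor signalling genes 18 fell and 0 rose in the libraries labelled allogeneic, with a median log2 fold change of −0.87 (camera adjusted p = 3.12e-09, adjusted p = 0.0645 with an estimated correlation). Cd4 itself, the co-receptor that defines these cells, fell from 183 ± 3.40 to 76.2 ± 2.72 FPKM (−1.25). Ptpn22, a phosphatase that restrains the receptor, fell by 1.84, Zap70, the receptor-proximal kinase, by 1.502 and Prkcq, a downstream kinase, by 1.30 on the log2 scale. The CD3 chains that carry the receptor all fell, though not equally, Cd3d by 1.25, Cd247 by 1.20, Cd3e by 0.93 and Cd3g by 0.88. Because of this common fall, T cell genes were also read relative to the CD3 chains, a scaling chosen after the data were seen that moved the median of all genes to 1.01. On that scale the median of the receptor signalling list turned to 0.20 with 12 genes higher and 7 lower, and Cd4 stood at −0.17, Zap70 at −0.44, Ptpn22 at −0.80 and Prkcq at −0.24. The list median lay below that of all genes, and camera still called the list lower. The CD3 chains themselves ran from −0.17 (Cd3d) to 0.19 (Cd3g), so values of that size lie near their own spread.

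**Figure D2:**
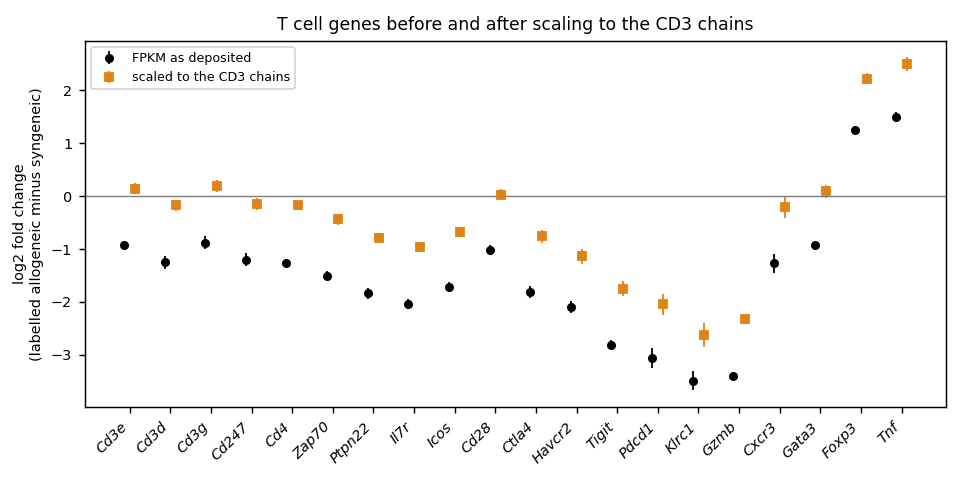
Log2 fold changes of 20 T cell genes, libraries labelled allogeneic minus libraries labelled syngeneic (n = 3 each), for FPKM as deposited (black circles) and for FPKM scaled to the CD3 chains (orange squares), with bars of 2 SE. Gzmb moved from −3.40 to −2.33 and Pdcd1 from −3.06 to −2.04, and Gata3 and Cd28 turned to 0.09 and 0.025.

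Genes of inhibitory receptors, follicular help and cytotoxicity were lower in the libraries labelled allogeneic. Of 15 inhibitory receptors and their regulators 13 fell and 1 rose (median −1.17, camera adjusted p = 3.36e-06, adjusted p = 0.0718 with an estimated correlation). Pdcd1 and Tigit led the falls, and Eomes, a transcription factor of effector and memory cells, rose by 0.80. All 12 measured follicular helper genes fell (median −1.31, camera adjusted p = 5.50e-07, adjusted p = 0.0645 with an estimated correlation). Among them Icos, a costimulatory receptor, fell by 1.71, Slamf6 by 1.52 and Tox2 by 1.48. Of 17 cytotoxic genes 15 fell and 1 rose (median −1.04, camera adjusted p = 2.10e-06, adjusted p = 0.0645 with an estimated correlation). Klrc1, an NK-type receptor, stood at 1.496 ± 0.314 against 27.0 ± 0.571 FPKM, and the lysosomal Lamp1 rose by 1.08. Beside these genes Cd8b1 stood at −1.60 and Cd8a at −1.43 relative to the CD3 chains. Of 19 type 1 helper genes 15 fell and 4 rose (median −1.16, camera adjusted p = 6.65e-05, adjusted p = 0.0645 with an estimated correlation). Havcr2, the receptor TIM-3, fell by 2.10 and Il18r1 by 1.72, and Tnf rose by 1.497 and Hlx by 1.18. Relative to the CD3 chains the medians of these 4 lists were −0.32, −0.39, −0.07 and −0.17, and the counts were more even. That scaling called 11758 genes higher and 511 lower and moved the median of all genes to 1.01. Camera still called the 4 lists lower. On that scale 8 inhibitory receptor genes were lower and 6 higher, 9 follicular helper genes lower and 2 higher, 7 of 16 cytotoxic genes lower and 5 higher, and 8 type 1 genes lower and 8 higher. Klrc1 stood at −2.62, Gzmb at −2.33, Pdcd1 at −2.04 and Tigit at −1.75, and Lamp1 at 2.16 and Hlx at 1.91.

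Foxp3, the defining transcription factor of regulatory T cells (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), rose from 5.99 ± 0.227 to 15.6 ± 0.203 FPKM (log2 fold change 1.25, SE 0.0436, limma adjusted p = 1.49e-06). Itgae, an integrin of tissue T cells, rose by 1.08, while Ctla4, an inhibitory receptor shared with activated cells, fell by 1.82. The regulatory T cell list as a whole had 10 genes lower and 3 higher of 17 (median −0.35, camera adjusted p = 0.00803, adjusted p = 0.0915 with an estimated correlation). Naive and memory genes fell in 11 of 16 and rose in 3 (median −0.92, camera adjusted p = 0.000149, adjusted p = 0.132 with an estimated correlation). Il7r, the interleukin-7 receptor of resting cells, stood at 41.1 ± 0.919 against 171 ± 9.84 FPKM, Bcl2, a survival gene, at −1.26 and Igfbp4 at 0.54 on the log2 scale. Costimulatory receptors fell in 11 of 13 (median −0.88, camera adjusted p = 1.47e-06, adjusted p = 0.0645 with an estimated correlation), with Cd2 at −1.23, Tnfrsf4 at −1.07 and Cd28 at −1.02. Relative to the CD3 chains the medians of these 3 lists turned to 0.54, 0.12 and 0.19, Cd28 turned to 0.025, and Cd28 and Tnfrsf4 (−0.03) were no longer called. The list medians lay below the 1.01 of all genes on that scale, and camera still called the 3 lists lower.

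Other helper programmes also differed, with list medians that were negative for FPKM as deposited and positive after scaling to the CD3 chains. Type 2 helper genes fell in 5 of 9 and rose in 2 (median −0.29, camera adjusted p = 0.0359, adjusted p = 0.339 with an estimated correlation). The interleukin-4 receptor gene Il4ra fell by 1.37 and the lineage factor Gata3 by 0.93, and Ccr4, a chemokine receptor, rose by 1.12. Type 17 helper genes fell in 6 of 8 and rose in 2 (median −0.73, camera adjusted p = 0.00775, adjusted p = 0.0915 with an estimated correlation). Csf2, a myeloid growth factor, fell by 2.01 and Batf by 1.34, and Ccr6 rose by 0.73. Early activation genes fell in 11 of 19 and rose in 6 (median −0.27, camera adjusted p = 0.0302, adjusted p = 0.176 with an estimated correlation). The phosphatase Dusp2 fell by 1.499 and the factor Irf4 by 1.44, and Cd44, an adhesion receptor of activated cells, and Fosb both rose by 0.63. Scaled to the CD3 chains, the medians of these 3 lists turned to 0.57, 0.30 and 0.59, and camera no longer called the type 2 (adjusted p = 0.157) and early activation lists (adjusted p = 0.209). Camera still called the type 17 list lower on that scale, where the median of all genes was 1.01. The type 2 list was also no longer called without replicate 2 of the libraries labelled allogeneic (adjusted p = 0.0554) or the early activation list after quantile normalization (adjusted p = 0.143). Many T cell lists share members, so their tests are not independent.

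Genes induced by interferons were lower in the libraries labelled allogeneic for FPKM as deposited, and their list medians turned positive after scaling to the CD3 chains. Of 26 interferon-gamma response genes 24 fell and 1 rose (median −0.99, camera adjusted p = 5.55e-10, adjusted p = 0.0645 with an estimated correlation). The guanylate-binding protein genes Gbp2 and Gbp4 fell by 1.81 and 1.51, with Gbp2 at 22.4 ± 0.752 against 81.2 ± 3.596 FPKM. Irf8, a factor of myeloid and dendritic cells, rose by 1.68. Of 27 type I interferon response genes 22 fell and 3 rose (median −0.65, camera adjusted p = 5.03e-07, adjusted p = 0.0915 with an estimated correlation). Oas1a, an antiviral enzyme, fell by 3.41 and Zbp1, a nucleic acid sensor, by 1.57, and Ifi44 rose by 0.66. Of 25 JAK-STAT genes 19 fell and 3 rose (median −0.48, camera adjusted p = 2.54e-06, adjusted p = 0.0645 with an estimated correlation), with the feedback inhibitor Socs3 at −1.83 and Stat4 at −1.34. Relative to the CD3 chains the medians of these 3 lists turned to 0.05, 0.37 and 0.56, while Oas1a (−2.82), Socs3 (−0.77), Gbp2 (−0.75) and Zbp1 (−0.52) stayed lower. That scaling moved the median of all genes to 1.01, above these 3 medians, and camera, which compares a list with other genes, still called the 3 lists lower.

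Survival and stress signalling genes were mostly lower for FPKM as deposited, and their list medians turned positive after scaling to the CD3 chains. Of 20 NF-kB genes 16 fell and 0 rose (median −0.30, camera adjusted p = 3.36e-06, adjusted p = 0.0645 with an estimated correlation). Bcl3 fell by 1.20 and the feedback inhibitor Tnfaip3 by 0.99. Targets of p53 fell in 13 of 18 and rose in 2 (median −0.47, camera adjusted p = 6.65e-05, adjusted p = 0.0915 with an estimated correlation), with Trp53inp1 at −1.12. Apoptosis genes fell in 12 of 23 and rose in 7 (median −0.30, camera adjusted p = 0.0378, adjusted p = 0.132 with an estimated correlation). The death inducers Bcl2l11 and Bbc3 fell by 1.86 and 1.58, and Bid rose by 1.21. The apoptosis call was lost without replicate 3 of the libraries labelled allogeneic (adjusted p = 0.0545) and after quantile normalization (adjusted p = 0.0522). Relative to the CD3 chains the medians of these 3 lists turned to 0.73, 0.58 and 0.69 and none of them was called by camera (adjusted p = 0.182, 0.171 and 0.128). The median of all genes moved to 1.01 with that scaling, above these 3 medians. On that scale Bcl3 (−0.19), Trp53inp1 (−0.05) and Tnfaip3 (0.093) were no longer called.

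Genes of proliferation and biosynthesis were higher in the libraries labelled allogeneic, in which Hbb-bs stood at 176 against 1.58 FPKM and Mpo at 674 against 42.6. Of 26 S-phase genes 25 rose (median 1.00, camera adjusted p = 1.59e-08, adjusted p = 0.0996 with an estimated correlation). Pola1, a DNA polymerase subunit, rose by 1.40, Uhrf1, which maintains DNA methylation, by 1.29 and the cell cycle factor E2f1 by 1.19. All 26 G2 and M phase genes rose (median 0.75, camera adjusted p = 3.61e-08, adjusted p = 0.132 with an estimated correlation). The checkpoint kinases Ttk and Bub1 rose by 1.30 and 1.24, and Top2a, a topoisomerase, stood at 81.9 ± 2.19 against 36.2 ± 1.73 FPKM. All 20 ribosome biogenesis genes rose (median 0.67, camera adjusted p = 1.77e-06, adjusted p = 0.0645 with an estimated correlation), led by Dkc1 (1.17) and Nop58 (0.96). Heat shock chaperones rose in 10 of 12 (median 0.78, camera adjusted p = 0.000508, adjusted p = 0.0897 with an estimated correlation). Hsp90aa1 stood at 461 ± 13.6 against 152 ± 1.04 FPKM and the mitochondrial chaperone Hspd1 rose by 1.51. Citric acid cycle genes rose in 14 of 15 (median 0.44, camera adjusted p = 0.000266, adjusted p = 0.0645 with an estimated correlation), led by fumarase, Fh1 (1.28). Respiratory chain genes rose in 20 of 24 (median 0.43, camera adjusted p = 0.000251, adjusted p = 0.0966 with an estimated correlation), led by Ndufa4 (0.99). Amino acid and one-carbon genes rose in 11 of 15 and fell in 1 (median 0.42, camera adjusted p = 0.0253, adjusted p = 0.179 with an estimated correlation). The folate enzymes Shmt1 and Mthfd1l both rose by 1.11, and Slc1a5, a glutamine transporter, fell by 0.42 and turned to 0.64 after scaling to the CD3 chains.

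Markers of other cell types moved with the groups. All 17 red cell genes rose in the libraries labelled allogeneic (median 2.11, camera adjusted p = 1.08e-07, adjusted p = 0.0645 with an estimated correlation). Globins held 0.109 to 0.114% of FPKM there against 0.00119 to 0.00149%. Macrophage and monocyte genes rose in 21 of 22 (median 1.74, camera adjusted p = 1.27e-08, adjusted p = 0.144 with an estimated correlation). Hmox1 stood at 155 ± 1.85 against 21.1 ± 0.789 FPKM, and the iron exporter Slc40a1 rose by 2.65 and the macrophage antigen Adgre1 by 2.25. Neutrophil and granule genes rose in 15 of 18 and fell in 1 (median 1.40, camera adjusted p = 7.03e-05, adjusted p = 0.15 with an estimated correlation). Mpo and Csf3r rose, and Chil3 stood at 34.6 ± 2.16 against 368 ± 19.3 FPKM. Mast cell and basophil genes rose in 10 of 12 and fell in 1 (median 0.80, camera adjusted p = 0.00806, adjusted p = 0.0915 with an estimated correlation), with the protease Mcpt4 at 2.20 and the receptor Kit at 1.51. Plasma cell genes went the other way, with 13 of 14 lower and 1 higher (median −1.47, camera adjusted p = 1.08e-07, adjusted p = 0.0645 with an estimated correlation). Ighg1 stood at 10.7 ± 0.913 against 1654 ± 62.95 FPKM, and Igha at 62.7 ± 0.719 against 43.8 ± 1.95. The 9 plasma cell genes that are not immunoglobulins all fell, with a median of −1.02 that turned to 0.014 after scaling to the CD3 chains. On that scale 8 of the 14 plasma cell genes were lower and 4 higher, with a median of −0.51, and 3 of 6 CD8 T cell genes were lower and 1 higher, with a median of −0.77. CD8 T cell genes fell in 6 of 7 and rose in 1 (median −1.04, camera adjusted p = 0.00475, adjusted p = 0.0915 with an estimated correlation), with Cd8b1, a CD8 chain, at 1.37 ± 0.146 against 11.8 ± 0.970 FPKM. After scaling to the CD3 chains, which raises most genes, camera no longer called the neutrophil (adjusted p = 0.0804) and mast cell lists (adjusted p = 0.105).

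**Figure D3:**
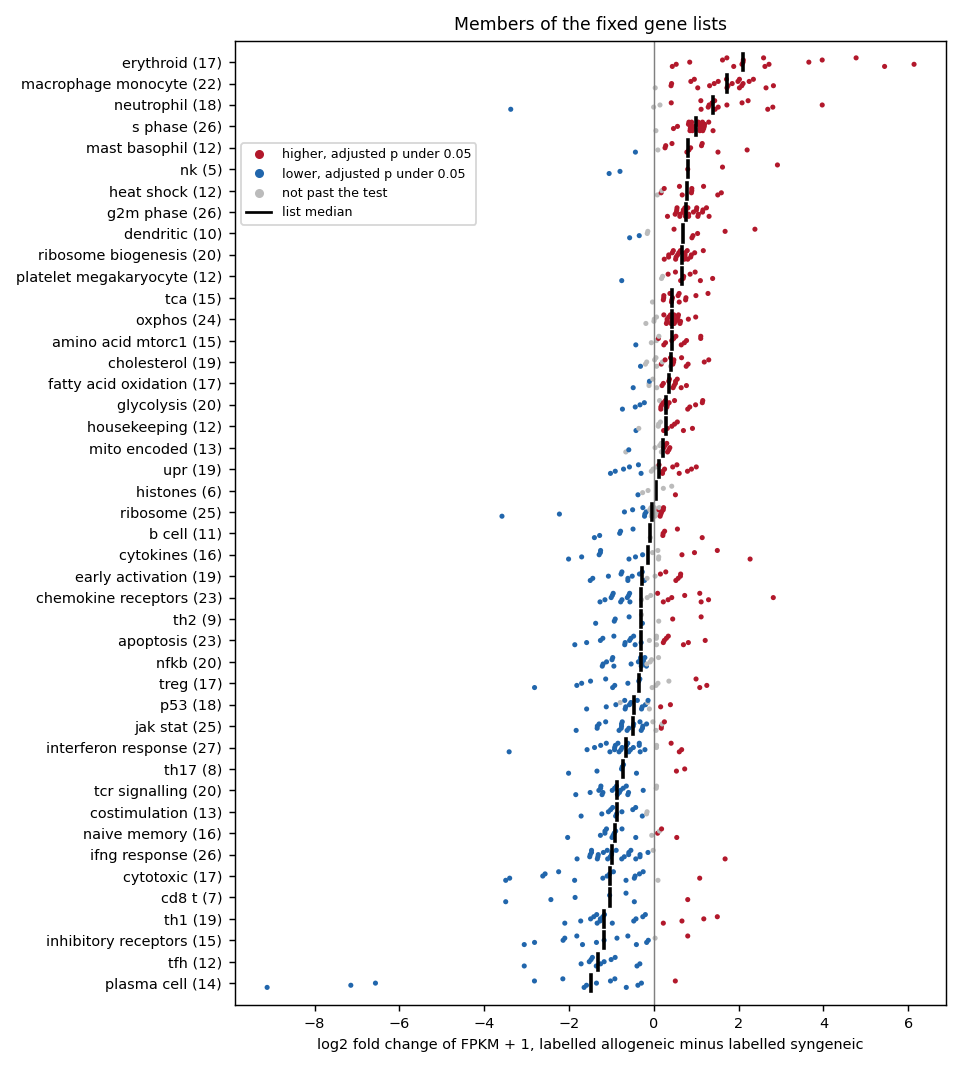
Log2 fold changes of FPKM + 1, libraries labelled allogeneic minus libraries labelled syngeneic (n = 3 each), for the measured members of 44 fixed lists, with 1 point per gene, black bars for list medians and the number measured in brackets. Red and blue points passed the limma test as higher or lower, and grey points did not. Medians ran from −1.47 for plasma cell genes to 2.11 for red cell genes, and scaling to the CD3 chains turned negative medians positive for the receptor signalling, naive and memory, costimulation, regulatory, type 2, type 17, early activation, interferon, JAK-STAT, NF-kB, p53 and apoptosis lists, among others. That scaling moved the median of all genes to 1.01.

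The other lists did not pass camera as sets, although many members passed limma singly. Glycolysis genes rose in 14 of 20 and fell in 4 (camera adjusted p = 0.0687), with Pgam1 at 1.15 and Pfkp at −0.74. Fatty acid oxidation genes rose in 11 of 17 and fell in 2 (camera adjusted p = 0.188), with Etfb at 0.77 and Slc25a20 at −0.49. Cholesterol synthesis and uptake genes rose in 11 of 19 and fell in 1 (camera adjusted p = 0.0593). Chemokine receptors and integrins fell in 11 of 23 and rose in 9 (camera adjusted p = 0.0579). Ccr3, an eosinophil receptor, rose by 2.82 and Ccr2, a monocyte receptor, by 1.29. Cxcr3, a receptor of type 1 cells, fell by 1.27 and S1pr1, the exit receptor of lymphoid organs, by 1.15. Cytokines fell in 8 of 16 and rose in 4 (camera adjusted p = 0.124), with Il10 at −1.70, Csf2 at −2.01 and Xcl1 at 2.27. Unfolded protein response genes rose in 10 of 19 and fell in 6 (camera adjusted p = 0.759), with the chaperones Calr at 1.00 and Canx at 0.89 and the regulator Xbp1 at −1.02. Ribosomal protein genes rose in 6 of 25 and fell in 8 (camera adjusted p = 0.0911), and histones rose in 1 and fell in 1 of 6 (camera adjusted p = 0.761). B cell genes were split with 5 higher and 5 lower of 11 (camera adjusted p = 0.297), with Bank1 at 1.14 and Cd22 at −1.28. NK cell genes rose in 3 and fell in 2 of 5 (camera adjusted p = 0.761), with the receptor Ncr1 at 2.91 and the kinase Txk at −1.05. Dendritic cell genes rose in 6 of 10 and fell in 2 (camera adjusted p = 0.294), with the progenitor receptor Flt3 at 2.38, and platelet genes rose in 9 of 12 and fell in 1 (camera adjusted p = 0.0547). Stromal genes, too few for camera, rose in 2 of 3, with Stab2 at 1.11 and Pdgfrb at 0.88. Mitochondrially encoded genes rose in 6 of 13 and fell in 1 (camera adjusted p = 0.408), and housekeeping genes rose in 7 of 12 and fell in 1 (camera adjusted p = 0.0687), with Tubb5 at 0.91 and B2m at −0.42. Some of these lists passed camera under other settings. Chemokine receptors passed when any 1 library other than replicate 1 of those labelled allogeneic was left out (adjusted p = 0.0358 to 0.0461). Cholesterol genes passed when any 1 of the libraries labelled allogeneic was left out (0.0219 to 0.0470), and ribosomal protein genes without replicate 3 of those labelled syngeneic (0.0188). Quantile normalization gave an adjusted p = 0.0249 for glycolysis, 0.0339 for mitochondrially encoded, 0.0412 for platelet and 0.00432 for housekeeping genes. Without a filter on low values it was 0.0455 for glycolysis, 0.0385 for cholesterol, 0.0341 for platelet and 0.0460 for both cytokine and housekeeping genes. Scaling to the CD3 chains gave 0.00230 for cytokines, turned Pfkp to 0.29, Slc25a20 to 0.47, Xbp1 to 0.055 and B2m to 0.67, and ended the calls of Xbp1, Cxcr3 (−0.21), S1pr1 (−0.08) and Txk (−0.12). With the replicate number as a block the platelet list had an adjusted p = 0.0455. Counts adjusted over the list alone were equal to these except for costimulatory receptors (12 lower), p53 targets (14 lower), ribosomal protein genes (4 higher), histones (0 lower), stromal genes (1 lower) and housekeeping genes (8 higher).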

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

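The voom test on recovered reads, the scaling to the CD3 chains and the subtraction of the median were chosen after the data were seen, and the other alternatives before. Requiring a log2 fold change of at least 1 left 1039 genes higher and 704 lower, a stricter threshold by construction. Between 4467 and 5181 genes were higher and 3033 and 3277 lower when each replicate was left out in turn, the share of superantigen-sensitive segments differed by −22.2 to −20.8 points, and lists numbered 11 to 12 higher and 19 to 21 lower. Voom shared 8026 calls with the limma result, all in the same direction, and quantile normalization 8052, of which 8035 had the same direction. Camera with an estimated correlation called 0 lists higher and 0 lower against 11 and 19, and fry, which does not compare a list with other genes, called 19 higher and 23 lower. Scaling to the CD3 chains gave 11758 genes higher and 511 lower, since it raises values in the libraries labelled allogeneic by construction, and turned these log2 fold changes from negative to positive: Gata3 0.093, Cd28 0.025, Pfkp 0.29, Eno1 0.64, Slc25a20 0.47, Acaa2 0.96, Sc5d 0.63, Slc1a5 0.64, Tnfaip3 0.093, Xbp1 0.055, Herpud1 0.16, Hist1h4i 0.56, mt-Nd3 0.36, Bst2 0.73, Itgb3 0.29, Cd200r3 0.33, Trbv12-2 0.21, Trbv19 0.41, Trbv2 0.27, Trbv31 0.60, Trbv20 0.37, Trbv13-3 0.32, Trbv13-1 0.76, Trbv17 0.35, Gbp2b 0.32, H2-D1 0.39, H2-Q4 0.27 and B2m 0.67. The same construction is the cause. It ended 18 further calls and gave 3. Apart from this scaling and the set tests, no alternative reversed a named gene or list, and each moved at most 5 of them past the threshold and at most 5 back. Libraries with the same replicate number did not deviate together (residual correlations of −0.03, 0.02 and −0.05), and the fit with the replicate number as a block called 5230 genes higher and 3443 lower. Tests and scalings meant for count tables, listed before the data were examined, were not run because the table holds FPKM. Depth limits some receptor segments, where Trbv26 rests on 0 to 5 reads per library labelled allogeneic.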

Other observations

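The segment classes, the strain, CD3, cell type and ribosomal protein tests were chosen after the results were seen, and the pseudogene test and the splits of the samples before. Antibody variable segments were broadly lower in the libraries labelled allogeneic. Donor strain differed between the groups, so a strain difference in mapping cannot be told apart here from one in expression. Of 114 measured Ighv segments 82 fell and 25 rose (median log2 fold change −2.44, and −1.48 relative to the CD3 chains), and of 95 Igkv segments 68 fell and 12 rose (−1.40, and −0.30 relative to the CD3 chains). Of 68 Trav segments of the T cell receptor alpha chain 40 fell and 1 rose (median −0.73), and of 22 Trbv segments 18 fell and 0 rose (−0.78), and relative to the CD3 chains these medians turned to 0.03 and 0.24.

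The strain-linked genes lie against the group labels. A possible explanation is correct labels with BALB/c reads that map less well to a C57BL/6 reference. Then the 6 genes other than Ighg2c known to be higher in C57BL/6 should be higher in the libraries labelled allogeneic. Yet 5 of them were called lower relative to the CD3 chains (median −2.45). All but Ly6a (−2.21) are Trbv segments, which deletion in BALB/c hosts could also lower, so only Ly6a tests the explanation freely. H2-Ea-ps, whose reads would then come from BALB/c cells in both groups, was higher by 2.60. The 5 class I genes all fell as deposited, with a median of −1.28, while this explanation would have them higher. Relative to the CD3 chains their median was −0.20, with 2 higher and 3 lower. All 5 lay below the 1.01 of all genes on that scale. Their expression may differ for other reasons, so they do not settle it alone. More T cell RNA in the libraries labelled syngeneic should move all Trbv segments alike, yet the superantigen-sensitive ones differed from the others by −2.97 in median (two-sided exact permutation of segments, p = 0.00171). Segments measured in the same libraries are not independent replicates, so this p-value does not measure the spread between libraries. Trbv23 and Trbv3 among the others fell further than Trbv12-1 and Trbv12-2 among the sensitive. An exchange of labels between the 2 groups, with which every direction would turn, may explain why 8 of the 9 strain genes went against the labels. Outside Ighg2c and the Trbv segments these were 2 of 3, and Gbp2b went with the labels. The sample titles carry S for the libraries labelled allogeneic and A for those labelled syngeneic. Where BALB/c donors and hosts were named, Trbv26 at 56.5, Trbv16 at 52.9 and Trbv15 at 39.9 FPKM were out of place. So was Ighg2c at 9605 FPKM, and these values argue against that label. An exchange also needs the other group out of place. For the segments this stays open, since deletion in BALB/c hosts could lower them there. BALB/c host cells there could also transcribe H2-Ea-ps, yet it stood at 133 FPKM, against 21.1 where all cells were named as BALB/c. Relative to the CD3 chains H2-Ea-ps was at 3.66, H2-Eb1 at 1.62 and H2-Ab1, H2-Aa and Cd74 at 1.00 to 1.28. More class II cells alone would move these genes alike, which argues against that account of H2-Ea-ps. Deletion does not cover Ly6a, which is not a receptor segment and stood at 32.9 against 329 FPKM.

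In a further pattern, of lower CD3 genes and differing T cell state genes, a lower share of T cell RNA in the libraries labelled allogeneic may account for the fall of the 4 CD3 chains, whose log2 fold changes had a mean of −1.06 and an SD of only 0.187. Whether it also accounts for the genes of the regulatory, follicular, inhibitory and cytotoxic lists stays open, since these lay on both sides of the CD3 chains, with Klrc1 at −2.62 and Foxp3 at 2.22 relative to them, and other cells can express many of them. A lower T cell share alone should raise the markers of all other cells alike, yet the red cell median exceeded that of the non-immunoglobulin plasma cell genes by 3.13 on the log2 scale, although the isolation kit should remove both. The labels give 1 donor strain per group, so strain and transplant type cannot be told apart, and a biological difference between transplants stays open.

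Ribosomal protein genes far lower in the libraries labelled allogeneic, among them Rpl29, Rps2 and Rpl26, have processed pseudogene copies. For the 7 that fell by at least 1 on the log2 scale, the gene and its pseudogenes were summed. The log2 ratio of the sums had a median of −0.346 and an SD of 0.917. That spread is too wide to decide for the set whether reads moved between copies. For Rps2 the sums were 596 ± 2.18 and 580 ± 14.2 FPKM (SD, n = 3), and for Rpl26 1248 ± 34.0 and 693 ± 51.6. The ratio for Rpl30 was 0.51, so for these genes the family as a whole did not fall. Rps18 kept a ratio of −1.41, Rpl29 of −1.26, Rpl21 of −1.23 and Rpl35a of −0.35. Across 786 pseudogenes with a tested parent, 91 rose and 33 fell by at least 1 on the log2 scale, and among the rises was Gm13394, a copy of Gapdh, at 419 against 47.1 FPKM. If reads moved from parents to raised pseudogenes in general, these parents should lie below other parents. They differed by −0.0344 in median (SE 0.113, permutation p = 0.583), so no such shift was seen for the parents as a set. Whether reads moved for some of them stays open, since they ran from −5.55 to 1.86, and 30.9% of them were called lower against 18.5%.

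The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The other splits mix the labelled groups, so they keep part of the group difference and put the rest into the spread within groups. Neither count below is therefore free of that difference. The real split gave 8914 genes and the highest of the others 0, so 1 of the 10 splits reached the real count. For gene lists the real split gave 30 and the highest other 27, and again 1 of the 10 splits reached the real count, so mixed splits also gave many list calls with camera.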
